A study of Mus musculus with 6 samples.

How the data were processed

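Gene expression was measured in the outflow tract of the embryonic mouse heart, the tube through which blood leaves the heart and which later divides into the aorta and the pulmonary trunk. Per the labels, hearts of CD1 embryos at embryonic day 10.5 were dissected into a superior and an inferior subdomain of this tube, and total RNA from pooled pieces was hybridised to Affymetrix Mouse Genome 430 2.0 arrays. There were 3 pools of superior and 3 pools of inferior tissue, numbered 1, 6 and 7 in both regions, so 6 arrays in all. The sample labels give 6 embryos of a litter per pool, whereas the series design text gives 7 dissected samples of each domain. The labels also name Trizol followed by a column cleanup where the design text names a column kit alone. Neither point is settled here. Nothing in the sources used here says that the pools came from separate litters. The p-values of single probe sets therefore measure the spread between these pools. Where the pool number is in the fit, they measure the spread of the region difference between these pools. The p-values of gene lists at a preset correlation set listed genes against other genes, and do not measure the spread between pools.

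The deposited values are linear intensity signals that the authors made with MAS5, per the submitters' processing notes, and the version is not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal per array and scales each array to a common level. In the deposited values, the mean of each array after trimming 2% at either end was 100. A signal is therefore relative to the rest of its array, and dim probe sets are noisy because a mismatch signal has been taken off. The arrays hold no count or depth, and their number limits the precision.

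The table has 45101 probe sets, of which 64 are control probe sets and were left out of the tests. Probe sets were named through the platform annotation given for the series: of the 45037 others, 34945 named 1 gene, 932 named several and 9160 were not named here. Symbols were checked by gene ID against a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them, and no coordinates are given. Signals were turned into log2(signal + 3.2), where 3.2 is the 25th percentile of all signals of probe sets other than controls. Fold changes are on this scale, which understates the change of dim genes. Probe sets were tested when their mean log2 value over all 6 arrays lay above the median over all probe sets, a signal of about 15.1, which left 22518 probe sets naming 11195 distinct genes. As a measure of background, the 27 Bacillus control probe sets whose transcripts were not among the spiked ones had a highest signal of 8.0, and a signal above that is called above background.

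Regions were compared as superior minus inferior with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust variance), with Benjamini-Hochberg adjustment over the 22518 probe sets and calls at an adjusted p threshold of 0.05. The planned design had no term for the pool number. Whether the pool numbers pair the arrays was then checked from the deviations of each array from the mean of its region. Same-numbered superior and inferior arrays deviated together, with correlations across probe sets of 0.79 for pool 1, 0.43 for pool 6 and 0.51 for pool 7. Because all 3 lay above the planned limit of 0.1, the numbers were taken to pair the arrays, which the labels leave open, and a fit with the pool number as a block, chosen as an alternative beforehand and called the paired fit here, is given beside the unpaired fit. Across regions, arrays of pools 6 and 7 with unlike numbers also passed the limit of 0.1. The correlation was 0.18 for superior 6 with inferior 7 and 0.20 for inferior 6 with superior 7. Passing the limit therefore does not by itself show that the numbers pair, although the same-numbered correlations were higher. Probe sets are not independent replicates, so these correlations describe the arrays only. Standard errors given with log2 differences are those of the paired fit with its eBayes variance, and not the plain standard error of the 3 pool differences. Array quality measures were compared by a two-sided exact permutation test, for which 3 arrays against 3 can give no p below 0.1.

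The gene lists for 25 pathways and cell types were tested with limma's camera at a preset inter-gene correlation of 0.01, using for each gene the tested probe set with the highest mean signal, and with Benjamini-Hochberg adjustment over the 25 lists. Of the 552 listed genes, 526 had a probe set of their own and 448 were tested. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. At the preset correlation, the camera p rests on the number of genes. With an estimated one it rests on the residual degrees of freedom of the arrays, 4 unpaired and 2 paired. A call lost there need not come from correlated genes. The unpaired estimate was 0.002 for FGF, -0.050 for neural crest and 0.289 for epicardium. The lists were anterior second heart field and outflow tract regulators, posterior second heart field, PPAR signalling and fatty acid handling, Notch pathway, semaphorins with plexins and neuropilins, retinoic acid, BMP and TGF-beta, WNT, FGF and hedgehog signalling, coronary vessel guidance and VEGF, cardiomyocyte sarcomere, chamber myocardium, smooth muscle, endocardium and endothelium, cushion mesenchyme, neural crest, epicardium, pharyngeal epithelium, erythroid cells, leukocytes, cell cycle, glycolysis and hypoxia, dissection stress, and extracellular matrix. A further list of sex-specific transcripts served only to look at the pools. The PPAR and Notch lists were included because the laboratory is known to have followed these pathways after this experiment.

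The tests, lists, filter, alternatives and rule for naming genes were fixed before the data were examined. The rule named the 12 genes with the largest fold change in each direction among called probe sets whose 3 values in a region all lay above those of the other. Where fewer than 5 genes passed in a direction, it named the 6 with the smallest p, said not to pass. It also named up to 4 called members of each list, or 2 by values only where none was called, and Pparg, Dlk1, Sema3c, Tbx1, Hoxb1, Isl1, Nkx2-5, Tnnt2, Myl7 and the sex-specific transcripts. Applying the same rule to the paired fit was decided after its values were seen. Ddx3y has no probe set of its own in the annotation and was not analysed here. One item of the rule is not reported here.

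The fits were tested on simulated data drawn from the means and spreads of the real arrays, with 200 of 22518 probe sets changed. The pool effects and residual spread of the paired fit were built in, so the comparison favours that fit by construction. Noise was independent between probe sets, so the numbers of false calls need not carry over to the real arrays. The unpaired fit recovered 0% of the probe sets changed by 0.5 on the log2 scale, 48% at 1, 88% at 2 and 96% at 3, with 0 false calls. The paired fit recovered 50%, 92%, 100% and 98%, with 34 false calls among 204, more than the threshold of 0.05 implies. In 20 simulated data sets with no changed probe set, the unpaired fit called 0 throughout and the paired fit called a median of 4.5 and at most 11. Alternatives were quantile, 75th percentile and cyclic loess normalization, offsets of 1 and 15.6 (the median signal), no filter and a filter at the top 25% of probe sets, eBayes without trend and robust variance, other thresholds, and leaving out each array. After the data were seen, the paired fit was also run under these settings and without each pool, and the unpaired fit without pool 1. Figures were drawn with matplotlib 3.10.9.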

Results

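The series asks how gene expression is regionalised within the outflow tract of the mouse heart. Superior and inferior subdomains were dissected from hearts at embryonic day 10.5, and 3 pools of each were measured on arrays. After scaling by the authors, the median signal of a probe set ranged from 13.9 to 17.6 over the 6 arrays, and between 58.4% and 63.1% of probe sets lay above the background level of 8.0.

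Of 13 measured genes of the epicardium, the sheet of cells that covers the heart, 12 were higher in the superior pools, although the call of this list was lost with an estimated correlation (adjusted p = 0.118). Aldh1a1 and Aldh1a2, genes of retinoic acid synthesis, were higher there, while the retinoic acid list was not called. Aldh1a2 is also one of these epicardial genes. Nrp2 and Sema3c were lower in the superior pools. With regions compared within each pool number, 36 probe sets of 28 genes differed, 17 genes being higher in superior and 11 lower. Tbx18, a T-box transcription factor of the epicardium, had a mean signal of 305.8 ± 123.2 (SD, n = 3) in superior and 85.3 ± 44.8 (n = 3) in inferior pools for its brighter probe set, a log2 difference of 1.86 ± 0.12 (SE; adjusted p = 0.00260). Nrp2, a co-receptor for semaphorins and VEGF, had a signal of 170.9 ± 85.7 in superior and 459.7 ± 174.4 in inferior pools for its brightest probe set, a log2 difference of -1.45 ± 0.12 (adjusted p = 0.00803), while another called Nrp2 probe set gave -0.99 ± 0.10. Both genes' differences held in each of the 3 pools, which their choice by a small paired p largely ensures.

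These calls come from the paired fit, which made 34 false calls among 204 in simulated data with the pairing built in. Without the pool number as a block, limma called 0 of 22518 probe sets, the smallest adjusted p being 0.755. At an unadjusted p threshold of 0.05 the unpaired fit passed 792 probe sets, 401 higher and 391 lower, where 1125.9 would pass by chance, and the paired fit passed 2473. The 3 superior values all lay above or all below the 3 inferior values for 9.21% of probe sets, where chance gives 10%. For these unpaired counts, both chance values take the 6 arrays as exchangeable. Arrays of a pool deviated together, so low counts do not show an absence of differences. The paired count rests on its settings: it was 22 with an offset of 1, 1 without the filter on dim probe sets, 2 in the top 25% by signal and 0 without the trend and robust variance, and it split into 26 higher and 12 lower under 75th percentile scaling. It was 9 without pool 1, of which 5 were among the 36, 231 without pool 6 and 113 without pool 7. The paired fit left 2 residual degrees of freedom, and fewer without a pool. Its counts therefore rest strongly on variance shared across probe sets, and a higher count without a pool is no stronger evidence.

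Among the genes higher in superior pools, the largest fold was that of Aldh1a1, a retinaldehyde dehydrogenase that makes retinoic acid. Its signal was 131.7 ± 42.8 in superior and 26.5 ± 19.4 in inferior pools, a 5.53-fold difference (log2 2.47 ± 0.28, adjusted p = 0.0411). Aldh1a2, the main retinoic acid synthesising enzyme of the early embryo, was 2.83-fold higher (log2 1.5 ± 0.19, adjusted p = 0.0411). Upk1b, a uroplakin of mesothelial cells, had 3 called probe sets, with log2 differences of 2.13 ± 0.25, 1.84 ± 0.23 and 1.41 ± 0.17. Irx4, a homeobox transcription factor of ventricular muscle, was 4.24-fold higher. Irx4 had a signal of 60.7 ± 27.95 in superior against 10.9 ± 0.42 in inferior pools (adjusted p = 0.0294). Ppp1r17, an inhibitor of protein phosphatases, was 4.25-fold higher. Dcn, which encodes the matrix proteoglycan decorin, was 3.39-fold higher (log2 1.76 ± 0.14, adjusted p = 0.00723). Abcc9, a regulatory subunit of ATP-sensitive potassium channels, was 3.27-fold higher, Slitrk5, a neuronal membrane protein, 2.97-fold, Tmem255a 2.85-fold, Apela, a peptide ligand of the apelin receptor, 2.17-fold, and Maf, a leucine zipper transcription factor, 2.16-fold. The signals of Aldh1a1, Ppp1r17, the dimmer Tbx18 probe set and the Upk1b probe set with the largest difference lay above background in 2 of the 3 inferior arrays, so these differences are less certain. The kinase gene Stk26 was 1.72-fold higher (log2 0.78 ± 0.09, adjusted p = 0.0294) and Tnfrsf19, a receptor of the tumour necrosis factor family, 1.70-fold. The protein kinase C gene Prkcb was higher too (log2 0.98 ± 0.13, adjusted p = 0.0417).

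Among the genes lower in superior pools, Efhd1, a calcium-binding protein of mitochondria, had a signal of 11.9 ± 1.62 in superior and 43.8 ± 7.54 in inferior pools (log2 -1.63 ± 0.18, adjusted p = 0.0294). Olfm1, a secreted olfactomedin protein, differed by -1.24 ± 0.17 (-0.97 ± 0.13 for its brighter probe set) and Lamb3, a laminin chain, by -1.26 ± 0.17 on the log2 scale, with adjusted p = 0.0417 for both. Tnnt1, the troponin T of slow skeletal muscle, had a signal of 482.1 ± 51.8 against 967.2 ± 171.5 (log2 -0.99 ± 0.10, adjusted p = 0.0237). Masp1, a protease of the complement system, differed by -0.99 ± 0.13, Apoe, a lipid carrier, by -0.93 ± 0.13, and Tril, a component of Toll-like receptor signalling, by -0.74 ± 0.10. Clstn2, a calsyntenin, and Phlda2, an imprinted gene, were also called, at -1.09 ± 0.13 and -0.75 ± 0.11, although their values in the regions overlapped across pools. Of the genes with the smallest p in the unpaired fit, Emilin2, Gata3 and Sowaha passed in neither fit. Emilin2, a matrix glycoprotein, had a log2 difference of 1.34 ± 0.19 (paired adjusted p = 0.0522), Gata3, a zinc finger transcription factor, -0.60 ± 0.10 (0.0761), and Sowaha -1.27 ± 0.20 (0.0780).

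**Figure D1:**
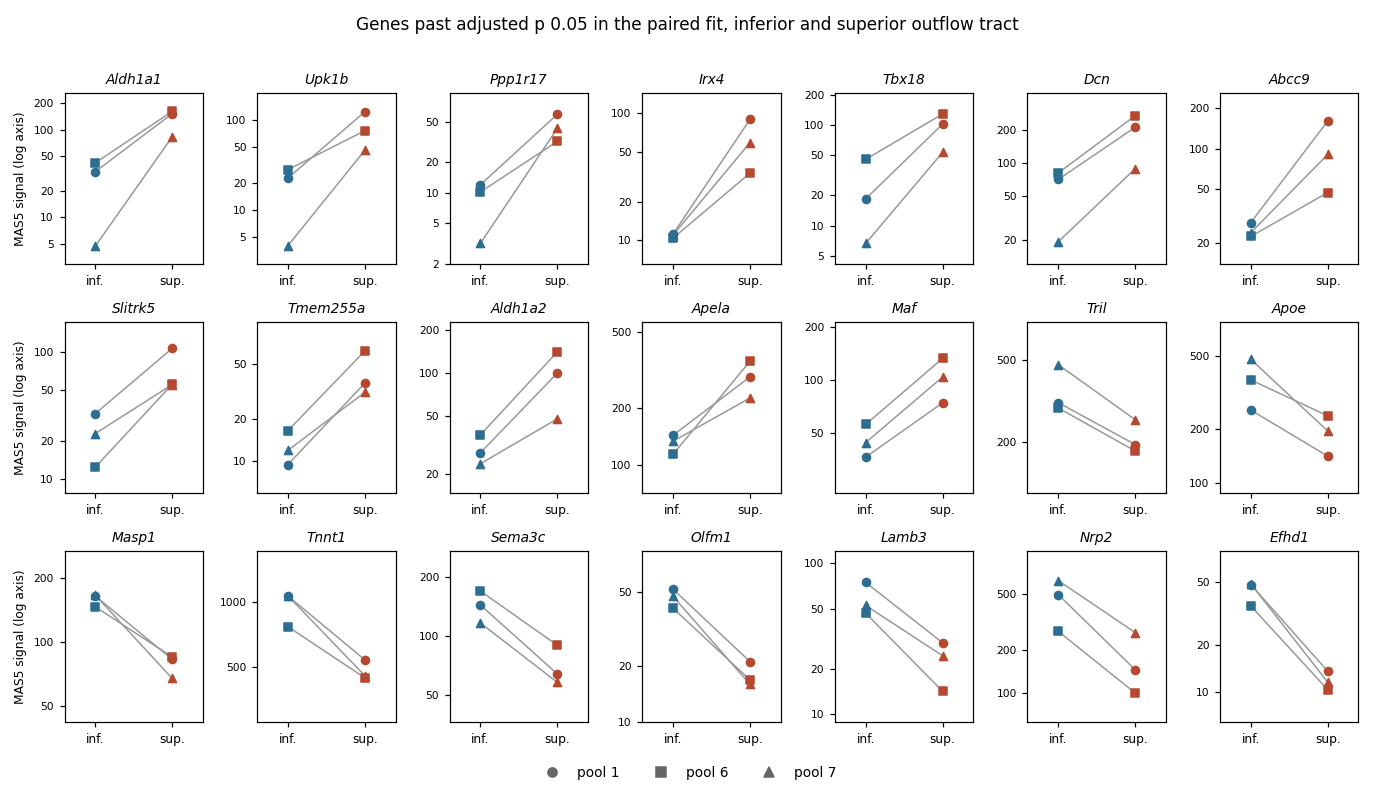
MAS5 signal (log axis) of 21 genes called in the paired fit, in the inferior and the superior outflow tract, with 1 line for each of the 3 pools. The genes were chosen for values that do not overlap between regions, so the 3 lines of a gene run the same way by selection. Levels differ between pools. The plotted Tbx18 probe set ranges from 53.4 to 128.1 in superior pools and from 6.7 to 45.6 in inferior pools.

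The epicardial list had the largest shift of the 25 lists. Of its 13 measured genes 12 were higher in superior pools, with a median log2 difference of 0.91 (camera adjusted p = 4.9e-12), and the call was lost with adjusted p = 0.118 with an estimated correlation. In the paired fit 4 members were called over all genes tested, and 11 when adjusted over the list alone, 10 higher and 1 lower. Without pairing these counts were 0 and 10. The 4 were Tbx18, Upk1b, Aldh1a2 and Tcf21, a helix-loop-helix factor of epicardial and pharyngeal mesoderm cells whose log2 difference was 0.69 ± 0.09 (adjusted p = 0.0479). The list's median difference was 0.98 in pool 1, 1.05 in pool 6 and 0.61 in pool 7. The superior 6 array stood apart in its hybridisation controls, whose signal was 1.63 times that of the median array, and in its highest signal of 8610. Without that array the list was still called (median 0.81, adjusted p = 2e-08).

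Chamber myocardium genes, which mark the working muscle of ventricles and atria, were higher in superior pools in 12 of 15 cases, with a median log2 difference of 0.40 (camera adjusted p = 3.9e-06; adjusted p = 0.0942 with an estimated correlation). Without the inferior 6 array the median fell to 0.20 (adjusted p = 0.00192), and it was 0.34, 0.59 and 0.29 in pools 1, 6 and 7. Irx4 was the 1 member called over all genes tested in the paired fit, and 8 were called when adjusted over the list alone, all higher. Without pairing these counts were 0 and 3. Genes of the sarcomere, the contractile unit of muscle, were higher in 25 of 30 cases by a smaller median of 0.19 (camera adjusted p = 8.2e-06; adjusted p = 0.0942 with an estimated correlation). Myl1, a myosin light chain, was called in the paired fit (log2 0.72 ± 0.10, adjusted p = 0.0417), and 5 sarcomere genes when adjusted over the list alone, against 0 without pairing. Myl2, the ventricular myosin light chain, had a signal of 6046 ± 962.5 against 4316 ± 296.8 (adjusted p = 0.234). The sarcomere call ended under quantile normalization (median 0.02, adjusted p = 0.649) and under cyclic loess (median 0.05, adjusted p = 0.179). Beside it, the superior 6 array had the 1.63-fold control signal, and the median sarcomere difference was 0.27 in pool 6, 0.12 in pool 1 and 0.15 in pool 7. Tnnt2, the cardiac troponin T, had signals of 4698 ± 358.7 and 4093 ± 182.8 (log2 0.20 ± 0.10, adjusted p = 0.492), of which quantile normalization turned the sign and another of its probe sets ran the other way. Myl7, the atrial myosin light chain, had signals of 5834 ± 997.1 and 4814 ± 219.7 (adjusted p = 0.426).

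Cell cycle genes were higher in superior pools in 23 of 24 cases, by a median log2 difference of 0.22 (camera adjusted p = 1.5e-08; adjusted p = 0.152 with an estimated correlation). No member was called over all genes tested. When adjusted over the list alone, 2 were called without pairing and 5 in the paired fit. Ccnd2, a D-type cyclin, had a log2 difference of 0.59 ± 0.11 (paired adjusted p = 0.124), and Ccna2, a cyclin of DNA replication and mitosis, 0.51 ± 0.09 (0.115). The list's median was 0.33 in pool 1, 0.31 in pool 7 and 0.02 in pool 6, and without pool 1 it was 0.14.

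FGF signalling genes were lower in the superior pools in all 16 cases, with a median log2 difference of -0.37 (camera adjusted p = 4.7e-10; adjusted p = 0.0550 with an estimated correlation). This was the 1 list called by fry without pairing (adjusted p = 0.0354), and fry called 0 lists in the paired fit. No member was called over all genes tested, and 9 were called in the paired fit when adjusted over the list alone, against 3 without pairing. Fgf8, a ligand that the second heart field needs for outflow tract growth, had a signal of 18.3 ± 7.06 in superior and 41.6 ± 17.1 in inferior pools (log2 -1.03 ± 0.17, paired adjusted p = 0.0932). The FGF targets Etv4 and Dusp4 had log2 differences of -1.06 ± 0.17 (0.0790) and -0.55 ± 0.09 (0.0732). The list's median was -0.38, -0.33 and -0.34 in pools 1, 6 and 7. Its estimated correlation of 0.002 lay below the preset 0.01, so correlated genes do not account for the larger p with an estimated correlation.

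Regulators of the anterior second heart field, the progenitor cells that add muscle to the outflow tract, were lower in superior pools in 10 of 13 cases (median log2 -0.31, camera adjusted p = 0.0062; adjusted p = 0.338 with an estimated correlation). In the paired fit 0 were called over all genes tested and 4 adjusted over the list alone, and 0 in either way without pairing. Isl1, a marker of these progenitors, had signals of 807.4 ± 163.1 and 1005 ± 242.1 (log2 -0.31 ± 0.08, paired adjusted p = 0.293). Tbx1, a T-box factor required for outflow tract growth, had signals of 31.9 ± 5.29 and 50.1 ± 19.0 (log2 -0.55 ± 0.23, 0.441), with -1.28 in pool 7 but -0.24 and -0.13 in pools 1 and 6. The cardiac transcription factor Nkx2-5 had signals of 408.0 ± 73.8 and 505.5 ± 72.7 (log2 -0.31 ± 0.09, 0.313). The list's median was -0.06, -0.22 and -0.36 in pools 1, 6 and 7, and it fell to -0.18 without the superior 6 array. Its call ended without the inferior 7 array (median -0.12, adjusted p = 0.366) and among the top 25% of probe sets by signal (median -0.09, 0.144).

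Semaphorins, their plexin and neuropilin receptors guide migrating cells and axons. Of this list's 18 measured genes 12 were lower in superior pools (median log2 -0.07), and the list was called in the paired fit (camera adjusted p = 0.0354, against 0.0536 without pairing; adjusted p = 0.318 with an estimated correlation in the paired fit). Nrp2 and Sema3c were called over all genes tested, and 4 members adjusted over the list alone, 3 lower and 1 higher. Without pairing these counts were 0 and 1. The higher one was Sema3d (log2 0.88 ± 0.23, adjusted p = 0.278 over all genes tested), and Nrp1 hardly moved (-0.02 ± 0.11). Sema3c, a secreted semaphorin needed for outflow tract septation, had a signal of 1311 ± 222.0 in superior and 2147 ± 291.5 in inferior pools for its brighter probe set (log2 -0.71 ± 0.10, adjusted p = 0.0484). Its dimmer probe set gave -1.01 ± 0.12 (adjusted p = 0.0294).

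Neural crest genes were lower in superior pools in 10 of 13 cases (median log2 -0.20, camera adjusted p = 0.00326; adjusted p = 0.118 with an estimated correlation). No member was called over all genes tested, and 4 were called in the paired fit adjusted over the list alone, against 0 without pairing. The homeobox gene Dlx2 had a log2 difference of -0.99 ± 0.20 (paired adjusted p = 0.155) and the neurotrophin receptor gene Ngfr -0.79 ± 0.21 (0.267). The list's median was -0.39, -0.08 and -0.41 in pools 1, 6 and 7, and -0.31 without the inferior 6 array and -0.32 without the inferior 7 array. Its call ended without the filter on dim probe sets (0.0753). Cushion mesenchyme, the tissue from which valves and septa form, had 14 of 21 genes lower (median log2 -0.14) and was called in the paired fit (camera adjusted p = 0.0338, against 0.0622 without pairing; adjusted p = 0.442 with an estimated correlation in the paired fit). Of its members 0 were called over all genes tested and 1 in the paired fit adjusted over the list alone, against 0 without pairing. Snai1, a driver of epithelial to mesenchymal transition, had a log2 difference of -0.52 ± 0.18 (0.380), and the fibrillar collagen gene Col3a1 0.21 ± 0.09 (0.434).

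BMP and TGF-beta signalling genes were lower in 23 of 27 cases, by a small median of -0.14 on the log2 scale (camera adjusted p = 0.0062; adjusted p = 0.221 with an estimated correlation). The ligands Bmp6 and Bmp5 had opposite differences of -0.63 ± 0.11 (paired adjusted p = 0.106) and 0.79 ± 0.17 (0.170). Members called in the paired fit adjusted over the list alone numbered 5, 4 lower and 1 higher, against 0 over all genes tested. The call ended without pool 1 (adjusted p = 0.0556), where the median was still -0.15, and the shift itself shrank without the superior 1 array (median -0.06, 0.225) and without the inferior 6 array (median -0.08, 0.0654). WNT signalling genes were lower in 20 of 26 cases (median log2 -0.10, camera adjusted p = 0.0442; adjusted p = 0.301 with an estimated correlation). This call was lost in 9 of the 19 other settings, without pool 1 (median -0.13, 0.0635) among them, and the median shrank to -0.04 without the superior 1 array and to -0.03 without the inferior 6 array. The WNT receptor gene Ror1 had a difference of 0.94 ± 0.17 (0.105) and was the 1 member called in the paired fit adjusted over the list alone, with 0 over all genes tested. Lgr5, a receptor for R-spondins, had a difference of -0.62 ± 0.19 (0.342). Without pairing both lists had 0 members called either way. The hedgehog list, with 8 of 9 genes lower, was not called (median log2 -0.06, camera adjusted p = 0.251, 0 members called either way). Its Gli3, a transcription factor of the pathway, had a difference of -0.35 ± 0.12 (0.378), and Smo, the transducer of the signal, -0.14 ± 0.10 (0.649), with its other tested probe set running the other way.

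In the retinoic acid list the dehydrogenase genes Aldh1a1 and Aldh1a2 were called over all genes tested in the paired fit, and 3 genes adjusted over the list alone, against 0 and 0 without pairing. The list was not called (camera adjusted p = 0.673). Its median log2 difference was -0.04, while its mean of 0.21 and the direction of the test were positive, with 4 of 14 genes higher. Rdh10, a retinol dehydrogenase of the same synthesis, had a difference of -0.20 ± 0.16 (0.674). The posterior second heart field list shares Aldh1a2, its 1 called member in the paired fit both over all genes tested and adjusted over the list alone. It had 8 of 11 genes lower, a median of -0.05 and a camera adjusted p of 0.673, and without pairing 0 and 1 members were called. Hoxa3, an anterior Hox gene, had a difference of -0.72 ± 0.34 (paired adjusted p = 0.486). Hoxb1, another gene of posterior second heart field progenitors, was at or below 6.2 on every array, under the background level of 8.0, and was not tested.

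The PPAR and Notch lists were chosen because the laboratory followed these pathways after this experiment, so they are not independent evidence. The PPAR and fatty acid list was not called, with 9 of 20 genes higher, a median log2 difference of -0.02 and a camera adjusted p of 0.327, and 0 members were called either way in both fits. Pparg, the nuclear receptor that drives fat cell formation, fell below the filter on dim probe sets. Its signals were 12.8, 2.6 and 1.6 in superior pools 1, 6 and 7 and 42.7, 19.1 and 13.8 in the inferior pools of the same numbers. That is a log2 difference of -1.76 ± 0.25, with an adjusted p of 0.197 in the paired fit without the filter, and its signal lay above background in 1 superior and all 3 inferior arrays. Fabp5, a fatty acid binding protein, had a difference of 0.29 ± 0.09 (0.370), and Cidea, a lipid droplet protein, -0.38 ± 0.21 (0.536). The Notch list had 16 of 21 genes lower (median -0.13, camera adjusted p = 0.0966) and 0 members called either way in both fits. Dlk1, a non-canonical Notch ligand, had signals of 750.9 ± 168.0 and 801.9 ± 311.0 (log2 -0.05 ± 0.12, 0.914), and its sign changed when single arrays were left out. Hey2, a Notch target of ventricular muscle, had a difference of 0.40 ± 0.09 (0.236), and the receptor gene Notch3 -0.36 ± 0.10 (0.283).

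**Figure D2:**
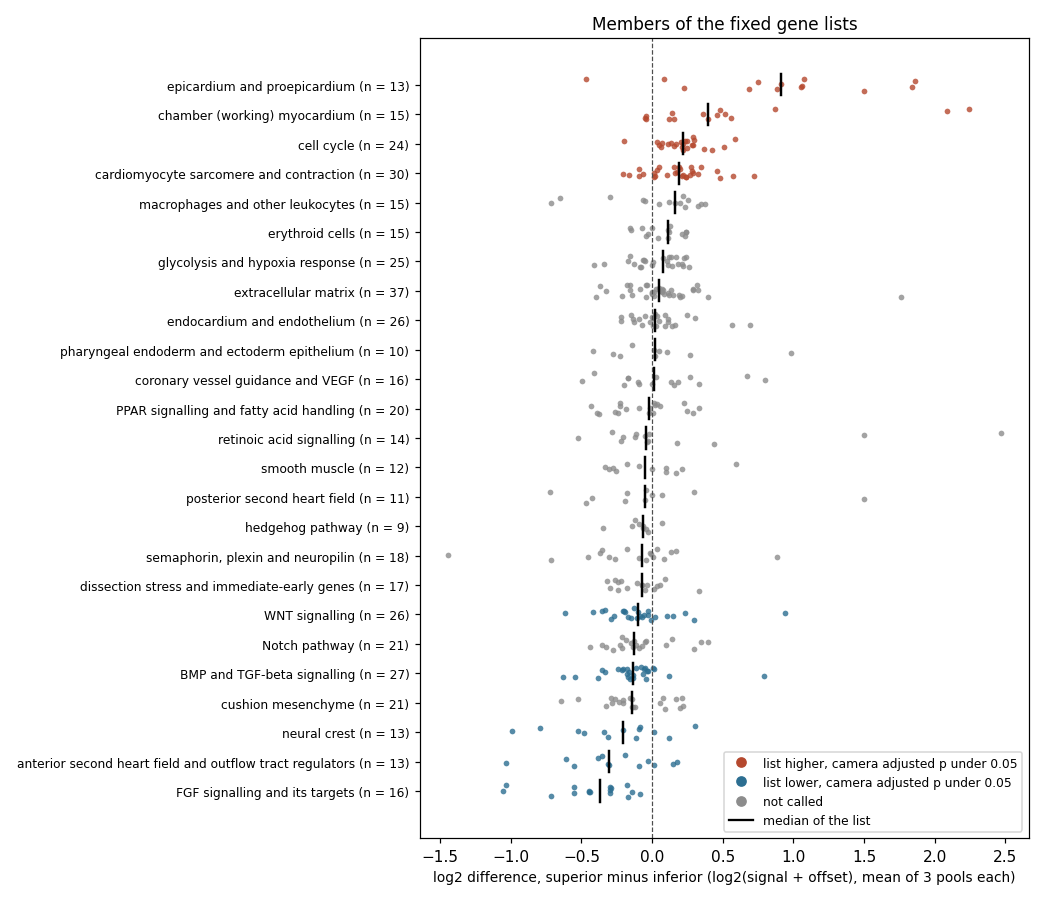
Log2 difference, superior minus inferior, of each measured gene (points) in the 25 lists, with the median of each list. The epicardial genes lie mostly to the right of 0 around a median of 0.91, and all 16 FGF genes lie to the left around a median of -0.37.

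No other list was called in either fit. The endocardial and endothelial list had 16 of 26 genes higher (median log2 0.02, camera adjusted p = 0.673), the smooth muscle list 5 of 12 (median -0.05, 0.973, the test's direction being positive), and the extracellular matrix list 22 of 37 (median 0.05, 0.234), with Dcn its called member. Adjusted over the list alone in the paired fit, 0, 1 and 5 of their members were called, and 0 without pairing. The smooth muscle genes Actg2 and Acta2 had differences of 0.59 ± 0.15 (paired adjusted p = 0.263) and 0.21 ± 0.09 (0.456), the latter with its sign turned by quantile normalization and opposite in its 2 other tested probe sets. The endothelial tight junction gene Cldn5 had 0.69 ± 0.35 (0.511), Egfl7, a secreted endothelial protein, -0.22 ± 0.12 (0.531), and the matrix glycoprotein gene Tnc -0.40 ± 0.10 (0.255). The coronary guidance and VEGF list had 8 of 16 genes higher (median 0.01, camera adjusted p = 0.973) and 3 members called in the paired fit adjusted over the list alone. Angpt1, a ligand of the endothelial receptor Tek, had a difference of 0.67 ± 0.12 (0.110), and Vegfa -0.41 ± 0.12 (0.319), with its other probe set running the other way.

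The erythroid list had 9 of 15 genes higher (median log2 0.11, camera adjusted p = 0.499). Its embryonic globin genes Hbb-bh1 and Hba-x had differences of 0.21 ± 0.12 (paired adjusted p = 0.542) and 0.23 ± 0.14 (0.593), and quantile normalization turned the sign of both. The leukocyte list had 10 of 15 higher (median 0.16, 0.673), with Coro1a, an actin regulator of white blood cells, at -0.65 ± 0.26 (0.429) and the coagulation factor gene F13a1 at -0.30 ± 0.24 (0.685). The pharyngeal epithelium list had 6 of 10 higher (median 0.02, 0.673) and medians of -0.02, 0.69 and -0.78 in pools 1, 6 and 7. Its keratin gene Krt7 had a difference of 0.98 ± 0.18 (0.122), called when adjusted over the list alone in both fits, and its claudin gene Cldn4 -0.42 ± 0.23 (0.539). The glycolysis and hypoxia list had 14 of 25 higher (median 0.07, 0.429), with Ldha, a lactate dehydrogenase, at 0.22 ± 0.09 (0.434). The dissection stress list had 12 of 17 lower (median -0.07, 0.0528), with the immediate-early gene Btg2 at -0.30 ± 0.15 (0.50) and the heat shock gene Hspa1b at -0.24 ± 0.12 (0.506). These lists, Krt7 aside, had 0 members called either way in both fits.

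Pool 1 stood apart from pools 6 and 7 in both regions. In a principal component analysis of the 22518 probe sets, the first component took 53.7% of the variance and set both pool 1 arrays, at 44.9 and 50.4, apart from the other 4, which lay between -27.97 and -19.81. Transcripts of the Y chromosome were at background in both pool 1 arrays: Eif2s3y, a translation factor gene, had signals of 2.2 and 1.1 there and 90.8 to 186.9 on the other 4. Kdm5d, a histone demethylase, had 0.5 and 1.1 against 68.2 to 109.6, and Uty, its relative, 0.2 and 1.6 against 36.1 to 53.0. Xist, the RNA that silences an X chromosome in females, had 2699 and 2685 against 925.5 to 1414. Their log2 differences between regions were 0.13 ± 0.19 for Eif2s3y, -0.01 ± 0.20 for Kdm5d, -0.04 ± 0.23 for Uty and -0.17 ± 0.09 for Xist, with no call, and signs that other settings turned. The control probe set for the 5-prime end of 18S ribosomal RNA read 31.0 and 21.3 in pool 1 and 454.6 to 752.4 elsewhere. The signal ratio of the 3-prime to the 5-prime control of Actb was 2.23 and 2.26 in pool 1 and 1.45 to 1.87 elsewhere, and that of Gapdh 1.30 and 2.21 against 0.83 to 0.90. For 12 such measures of array quality the exact permutation test between regions gave p-values from 0.2 to 0.9, all 0.9 after adjustment. This test leaves out the pool numbers and can give no p below 0.1, so it does not exclude a difference. Within the pools, 4 measures were higher in superior in all 3: the highest signal, the 3-prime and 5-prime 18S controls and the ratio of the 3-prime to the middle control of Actb, at 1.70 against 1.52, 1.53 against 1.32 and 1.43 against 1.37 in pools 1, 6 and 7. The 75th percentile of the signals was lower in all 3, at 91.4 against 92.8, 94.9 against 97.9 and 96.1 against 99.6.

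**Figure D3:**
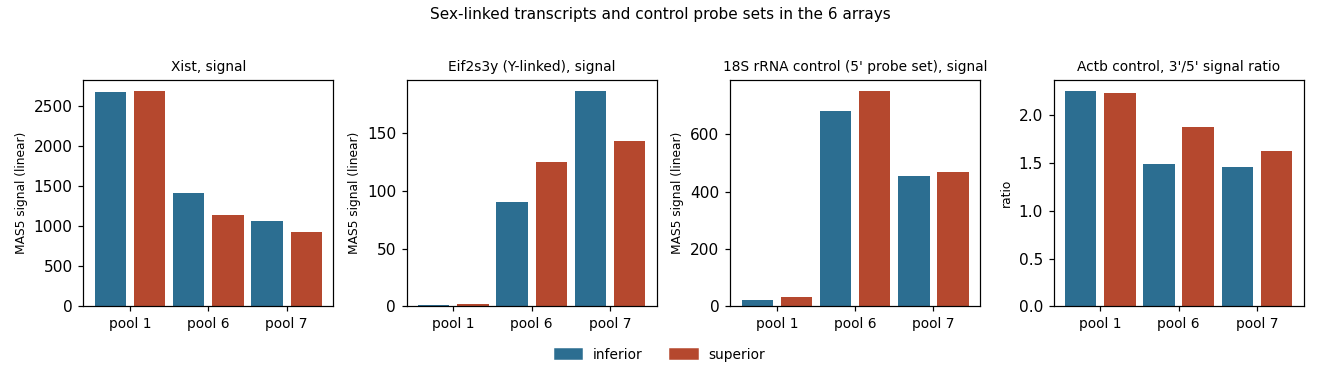
Signals of Xist, Eif2s3y and the 5-prime 18S control, and the Actb 3-prime to 5-prime ratio, on the 6 arrays. Both pool 1 arrays, superior and inferior, stand apart from the other 4 in each panel, as for Eif2s3y with 2.2 and 1.1 against 90.8 to 186.9.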

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

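The paired fit under the other settings and without each pool, and the unpaired fit without pool 1, were run only after the data had been seen, and the remaining settings had been chosen beforehand. The cause of the shifts below was not tested.

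Without pairing, limma called 0 probe sets in all other settings, and 469 (top 25% by signal) to 1644 (no filter) passed the unadjusted threshold. With the pool number as a block it called 36. The paired count was 37 with quantile normalization and the median offset, 38 with 75th percentile scaling and cyclic loess, 22 with an offset of 1, 22 at 2-fold or more, 74 at a threshold of 0.10, 2 in the top 25% by signal, 1 without the filter and 0 with plain variance. Without 1 pool it ran from 9 (pool 1) through 113 (pool 7) to 231 (pool 6), with fewer residual degrees of freedom than the 2 of the full paired fit. Of the probe sets followed for the genes named by the rule, 28 passed the threshold only with pairing. The remaining called probe sets, such as those of Prkcb, Clstn2 and Phlda2, were also called only with pairing. Among the camera calls of the lists, pairing changed only those of the semaphorin and cushion mesenchyme lists.

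Camera called 9 lists without pairing, 4 higher and 5 lower (3 and 6 under quantile and cyclic loess normalization), and 8 to 13 elsewhere, except 0 with an estimated correlation and 1 with fry. In the paired fit it called 11 lists, 8 to 12 elsewhere, except 0 with an estimated correlation and 0 with fry. No called list changed direction. With the estimated correlation in the paired fit, the adjusted p of every list was 0.286 or more. Over the other settings of the unpaired fit and the paired fit with the preset correlation, the adjusted p ran from 4e-16 to 0.118 for epicardium, 2.1e-07 to 0.0942 for chamber myocardium, 2.7e-06 to 0.649 for sarcomere, 1.3e-09 to 0.152 for cell cycle, 3.3e-11 to 0.0550 for FGF, 0.000317 to 0.502 for the anterior second heart field, 0.00141 to 0.118 for neural crest, 4e-05 to 0.225 for BMP and TGF-beta and 0.000372 to 0.412 for WNT. The WNT call was also lost without the filter (0.0761), with all probe sets of a gene averaged (0.107) and without the superior 1 (median -0.0450, 0.273), inferior 6 (-0.0317, 0.412), superior 7 (-0.0926, 0.116) or inferior 7 (-0.121, 0.0627) array.

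Of 1220 values of named genes in other settings, 1167 kept their direction and side of the threshold and 25 changed sign, none of them past the threshold. Quantile normalization turned Acta2 (-0.0396), Hbb-bh1 (-0.0278), Hba-x (-0.0208), Tnnt2 (-0.0291) and Kdm5d (0.0227). Kdm5d also turned under 75th percentile scaling (0.0210), cyclic loess (0.0604) and the median offset (0.0352), and Uty under cyclic loess (0.0376) and the median offset (0.0600). Without pool 1, F13a1 (0.0157), Kdm5d (0.0942) and Uty (0.189) turned. Without 1 array each, log2 differences ran from -0.271 to 0.246 for Dlk1, -0.632 to 0.208 for Xist, -1.52 to 1.69 for Eif2s3y, -1.47 to 1.56 for Kdm5d and -1.07 to 1.22 for Uty. Genes below a stricter filter have no value there. Between 58.4% and 63.1% of probe sets lay above background, which limits what dim genes such as Pparg can show.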

Other observations

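The tests of the 3-prime bias of pool 1 and of the FGF list against the outflow tract list, and the counts of splits for called probe sets with and without pairing, were chosen only after the results were seen, and so were the genes named in the next paragraph and the comparison of array quality within pools.

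At a looser adjusted p threshold of 0.10, the paired limma fit passed 74 probe sets of 60 genes, 27 higher and 33 lower in superior pools. Between the thresholds, genes with higher signal in superior pools were Nppa, a natriuretic peptide of chamber muscle, at 162.9 ± 125.5 against 25.2 ± 8.02 (SD, n = 3; log2 2.24 ± 0.30, adjusted p = 0.0622), Efnb3, an ephrin ligand of cell guidance, at 252.9 ± 67.7 against 117.5 ± 16.1 (0.0506), Dsc2, a cadherin of desmosomes (log2 1.16, 0.0505), and Lhx9, a LIM homeobox gene (1.3, 0.0625). Genes with lower signal there included the GABA receptor subunit gene Gabrb1 at 40.4 ± 6.19 against 79.5 ± 13.7 (-0.92, 0.0506), the ion transporter gene Slc12a2 (-0.79, 0.0506), the collagen gene Col12a1 (-0.77, 0.0707), the homeobox gene Barx1 (-1.33, 0.0934), the connexin gene Gja3 (-0.79, 0.0909) and the neural adhesion gene L1cam (-0.70, 0.0892). Mybpc1, which encodes the myosin-binding protein C of slow skeletal muscle, was 452.1 ± 24.8 against 702.7 ± 143.7 (-0.61, 0.0975).

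Epicardial and chamber genes were both higher in superior pools. For the epicardial genes, the scaling of the arrays or the superior 6 array cannot be the whole cause. Their list kept a median paired log2 difference of at least 0.839 under 3 normalizations and without pool 6. The muscle lists were not part of this test. Under quantile and cyclic loess normalization the chamber median stayed at 0.38 and 0.37, while the sarcomere median fell to 0.02 and 0.05. More epicardial cells in the superior pieces may contribute: 11 epicardial transcripts of a separate marker list had a median difference of 0.2488, with 9 higher, but 5 of them are also in the fixed list, the other 6 had a median of 0.16, and the abundant Clu, at 2037 against 2805, ran the other way. Pieces of chamber wall may contribute too: 14 abundant ventricular and atrial transcripts, 13 of them shared with the fixed lists, had a median of 0.1982 with 13 higher, while Ttn, at 2664 against 2762, was not. Some bright transcripts of other kinds shifted as much (Hbb-bh1 0.21, Col3a1 0.21, Ldha 0.22), while others such as Tnc (-0.40) did not. Hbb-bh1 moved mainly in pool 6 (0.51, against 0.13 and -0.01 in pools 1 and 7). These transcripts are single examples, and no set of like brightness was compared. Whether the median of 0.1982 is particular to chamber muscle is therefore not settled. The cut fixed beforehand for the marker medians lay between them: the epicardial 0.2488 passed and the chamber 0.1982 fell just short. The 6 epicardial transcripts outside the fixed list also fell short, a condition that the rule fixed beforehand did not hold. Neither marker test is therefore taken to decide. In pooled tissue a different cell makeup and a regional difference in expression, which was not tested, cannot be told apart.

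Pool 1 stood apart from pools 6 and 7 in both regions, with 2654 probe sets called between them by limma, 611 higher and 2043 lower in pool 1. As same-numbered arrays are taken as paired, this sets 2 arrays of a single pool against 4 arrays of 2 pools, so the count describes these pools and holds no spread between pools of the first kind. The sex of the embryos cannot be the whole cause, as 2648 of the called probe sets lie outside the sex-specific list, and the 5-prime 18S control read 31.0 and 21.3 in pool 1 and 454.6 to 752.4 elsewhere. A spread between pools for other reasons would itself be a further cause. A stronger 3-prime bias of the pool 1 RNA is a candidate explanation: the lowest Actb ratio in pool 1 was 1.19 times the highest elsewhere, and both Gapdh ratios also lay above the rest. In 1187 genes with a called and another bright probe set, the shifts of the 2 differed by a median of 0.9353 on the log2 scale. The first was chosen for its shift, with a median size of 0.93 against 0.16 for the other, so this comparison decides nothing, and loss of parts of transcripts in labelling stays open. A difference between litters was not tested.

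All 16 measured FGF genes were lower in superior pools. Dilution of outflow tract cells by other tissue could lower them together with other outflow tract genes. With the 1 shared member left out, 15 FGF genes had a median of -0.30 and 12 outflow tract genes -0.25, a difference with a two-sided permutation p of 0.424 over genes, which are not independent. This does not separate dilution from lower FGF signalling, which was not tested.

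Other splits of the 6 arrays, 3 against 3, number 10 with the real one, too few for a share under 0.05. Without pairing the real split called 0 probe sets, so all 10 necessarily give as many and the count tests nothing there. For gene lists, 3 of the 10 gave as many as the real 9, the highest other being 10, from superior 1 with both pool 6 arrays against the rest. Splits with both pool 1 arrays on a side passed 2017 to 3149 probe sets at the unadjusted threshold, against 792 for the real split, a structure that follows the pools. In the paired fit, 4 splits part all 3 pools, also too few, and 1 of the 4, the real one, gave its 36 probe sets, the highest other giving 1. The real split gave 11 lists there and the highest other 6.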
